A study of Mus musculus with 8 samples.

How the data were processed

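RNA was taken from whole 4MOSC1 tumours, by homogenization in TRIzol, phenol and chloroform extraction and column purification with DNase treatment, per the labels' protocols. Tumour cells were implanted in the buccal space of female mice aged 4 to 6 weeks, and mice were randomized when tumours averaged 10 to 20 mm3. The groups, 4 vehicle and 4 CXCL10 tumours, were taken from the sample titles, which also give day 10 as the day of collection, as does the series design. The source labels instead give days 10 to 13 for the vehicle tumours and 14 to 17 for the CXCL10 tumours, increasing by 1 with each sample. The titles were followed. If the source labels were right, day and treatment would be confounded. The labels number the tumours within each group and do not state that each came from its own mouse, so p-values measure the spread between these tumours.

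The deposited values were log2 normalized counts of 693 genes in 8 tumours, in columns named by sample. Per the file headers, the panel held 782 probes: 748 endogenous, 20 housekeeping, 6 positive control and 8 negative control probes. The authors' flags mark 55 endogenous probes as pruned, which leaves the 693, and mark 6 of the 20 housekeeping genes as used in normalization (Polr2a, Eef1g, Nubp1, Sap130, Rpl19 and Hdac3). The instrument, software and versions used by the authors are not given in the sources used here. The authors also deposited a coefficient of variation in percent for each probe. For the 6 housekeeping genes flagged as used it lay between 5.04% and 9.34%. Another 16 value columns of the deposited tables carry lane names that match no sample label, and they were not used. Entrez identifiers were taken from the deposited annotation of gene symbols. No coordinates are given, since no genome build is named.

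Within each tumour the deposited values, taken out of log2, were whole multiples of 1 step per tumour (0.919 to 1.09), so that whole counts could be recovered. With a tolerance of 0.02 counts, 100% of values came out whole in every tumour. The recovered counts gave the authors' coefficient of variation in 693 of 693 genes within 0.02 percentage points. The authors' normalization therefore acts as 1 factor per tumour. Recovered totals cover the endogenous genes that were kept. Counting error is small for most genes, with median counts between 391 and 471 per tumour, and large for genes such as Cd96, with 78 counts over the 4 vehicle tumours. Intervals from counts cover counting error only.

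A count-based test had been chosen before the data were examined, with limma on log2 values as its replacement if no file held whole-number counts. That condition was not met as written, since raw counts were deposited and whole counts could be recovered. The columns of raw counts matched no sample by name and were not used. The recovered counts would have allowed a count model, but were used with voom only, and edgeR and DESeq2 were not run. Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on the deposited log2 values. Group was the only term, with Benjamini-Hochberg adjustment over 693 genes. The variance model of limma had not been written down in advance. A fit with a mean-variance trend was seen first (0 genes at an adjusted p under 0.05), and the plain eBayes fit, which called 2 genes, was settled on after that, so both are given side by side. The planned filter compared counts with the negative control probes. It was not run, since their counts lay in the columns that were not used. The filter planned for files without such probes, a count of at least 20 in at least 4 tumours, removed 0 genes. Whether low genes lay above probe background was therefore not assessed. Vehicle tumours had counts of 16 to 23 for Cd96 and 21 to 23 for Aire. Fold changes are CXCL10 over vehicle.

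Before the data were examined, 28 gene lists were fixed, 14 of cell type markers and 14 of pathways and gene families. Skeletal muscle markers had no measured member, which left 27 lists with at least 3 members. Lists were tested with fry for a shift in 1 direction, adjusted over the 27 lists. Single genes were also adjusted over their list alone. That adjustment covers neither the 27 lists nor the panel, so some genes can pass within a list by chance. Fry's test compares a list's genes between groups and does not set the list against other genes. Some genes belong to more than 1 list. The rule for named genes was also fixed: the CXCR3 ligands and receptor, the 8 to 12 genes of smallest p in each direction (those that did not pass are said not to have), the 3 genes of smallest p in each list, and any gene with a count of 5 or fewer, of which there were 0. This gave 86 genes, and the text gives values for part of them. Members counted within a list are named as well. Clashes of near-identical probes within the Klra, Klrc and H2 families were not assessed.

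Other settings chosen before the data were examined were other count filters, a pseudocount of 1, a replicate block, leaving out each tumour in turn, an adjusted p under 0.10 and camera. The mean-variance trend, voom, median-of-ratios scaling, panel median centring, quantile normalization and fry's test of change in either direction were added after the data had been seen. Single values per tumour were compared with exact permutation tests, two-sided over 70 assignments. The gene test was checked on simulated data built from the means and spreads of these 8 tumours, in 20 runs of 693 genes. Counting noise was drawn on top of spreads that already contained it. Simulated genes therefore varied more than the real ones, above all at low counts. Summed over the runs, 9860 genes were unchanged, and 1340, 1340 and 1320 were changed by a log2 of 0.5, 1 and 1.5. The test called 52.5%, 91.3% and 98.7% of the changed genes in that order, and 3.12% of its calls were false. The share called depends on how many genes are changed, so these figures need not hold for the real tumours. The simulated genes varied independently of each other, which real genes do not. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for recovery of counts and plots. Correlations between the log2 values of tumours ran from 0.976 to 0.991 within groups, and chi-square per degree of freedom between the counts of 2 tumours of a group was at least 20.9, so that no 2 tumours agreed within sampling noise.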

Results

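Whole tumours of 4MOSC1, a mouse oral squamous cell carcinoma line, were grown in the cheek of female C57BL/6N mice, and their RNA was read with a targeted panel made up largely of immune genes. The chemokine CXCL10, which draws activated T cells and NK cells through its receptor CXCR3, had been injected into 4 tumours at 10 µg in 50 µl of buffer on days 3, 6 and 9 after implantation. The vehicle group of 4 tumours had received the buffer alone. Tumours of both groups were titled as collected on day 10. Levels of 693 genes were given for every tumour. Whole probe counts recovered from those levels summed to between 973697 and 1167694 per tumour, with means of 999440 ± 23296 (SD, n = 4) in vehicle and 1109238 ± 59035 (SD, n = 4) in CXCL10-treated tumours. The lowest count of any gene was 6.

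The comparison asked which panel genes differed in RNA level between CXCL10-treated and vehicle-treated tumours. Cd96 (Entrez 84544), a receptor of T cells and NK cells, rose 1.77-fold, from a log2 level of 4.31 ± 0.19 to 5.13 ± 0.12 (SD, n = 4 each). Il18r1 (Entrez 16182), a chain of the interleukin-18 receptor, rose 1.51-fold, from 8.80 ± 0.048 to 9.39 ± 0.025 (SD, n = 4 each). In both genes all 4 treated tumours lay above all 4 vehicle tumours. Counts of Cd96 were only 16 to 23 in vehicle and 33 to 40 in treated tumours, and probe background was not assessed. The log2 differences were 0.82 (SE 0.13) for Cd96 and 0.59 (SE 0.099) for Il18r1, each with a limma adjusted p = 0.0462 over the 693 genes. No gene fell at that threshold of 0.05. Unadjusted p lay under 0.05 for 104 genes with higher and 28 genes with lower levels after CXCL10.

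Both calls lay close to the threshold: the count of called genes was 0 with a mean-variance trend (lowest adjusted p = 0.0575) and 0 with voom weights on the recovered counts (lowest adjusted p = 0.0641). Il18r1 also missed the threshold when any 1 of the 8 tumours was left out, with adjusted p from 0.0548 to 0.202, and Cd96 when any tumour except vehicle tumour 2 was left out, with adjusted p from 0.0380 to 0.179.

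**Figure D1:**
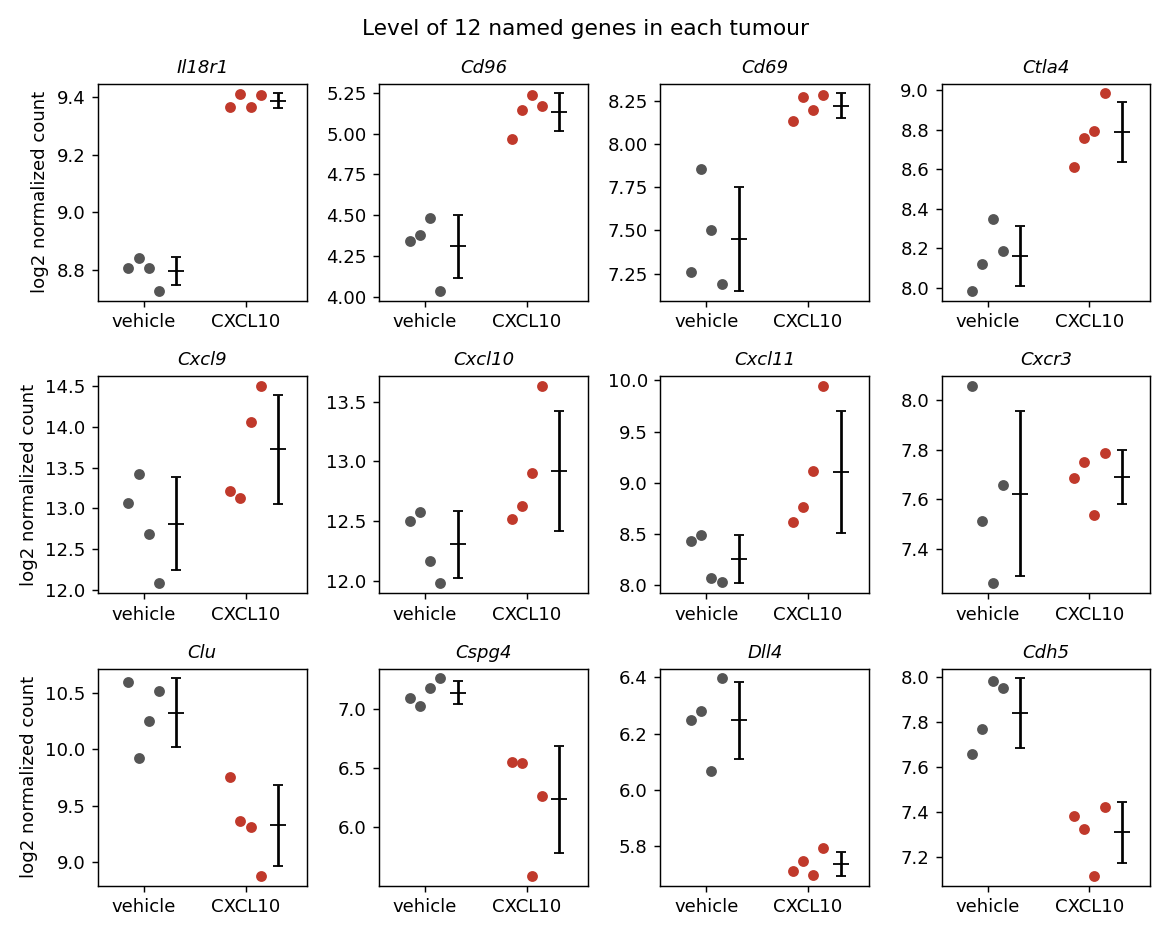
Levels of 12 genes in each tumour, as log2 normalized count (vertical axes, not starting at 0), for 4 vehicle tumours (grey) and 4 CXCL10-treated tumours (red), with the group mean and SD in black. Il18r1 and Cd96 passed the test over all genes, at log2 differences of 0.59 and 0.82, and the other 10 genes did not.

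Other genes of small p did not pass the test. On the higher side Cd69, an early activation marker of lymphocytes, had a log2 difference of 0.77 (SE 0.15) and Ctla4, an inhibitory receptor of T cells, one of 0.62 (SE 0.13), both with a limma adjusted p = 0.0915. Nlrc5, the transactivator of MHC class I genes, stood at 0.68, Slamf1, a co-receptor of lymphocytes, at 0.82, Aire, a transcription factor best known from the thymus, at 0.51, and the kinase Ripk2 at 0.66, with adjusted p from 0.120 to 0.123. On the lower side Clu, which encodes the chaperone clusterin, had a log2 difference of -0.999 (SE 0.21, limma adjusted p = 0.0915), from 10.32 ± 0.31 to 9.33 ± 0.36 (SD, n = 4 each). Dll4, a Notch ligand of sprouting vessels, stood at -0.51, Cspg4, a marker of pericytes, at -0.90, Cdh5, the cadherin of endothelial junctions, at -0.53 and Col4a1, a collagen of basement membranes, at -0.50. Mmp9, Eng and Tgfb3 followed at -0.53, -0.41 and -0.39. None of these 8 lower genes passed the test. The groups did not overlap in any tumour for 54 genes with higher and 21 genes with lower levels, where chance gives 19.8 genes in all on average (2.86% of those measured). Genes vary together between tumours, so chance counts can lie far from that average, and an excess over chance was not tested.

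The transcripts of the injected chemokine's own axis did not pass the test over all genes. Cxcl10 itself (Entrez 15945) had a mean log2 level of 12.31 ± 0.28 in vehicle and 12.92 ± 0.50 in treated tumours (SD, n = 4 each), a difference of 0.61 (SE 0.24, limma adjusted p = 0.217). Cxcl9 and Cxcl11, the other interferon gamma-induced genes of the CXCR3 ligand family, differed by 0.91 (SE 0.35) and 0.85 (SE 0.27), with limma adjusted p of 0.208 and 0.167. These are RNA levels, and whether working ligand protein was made from any of these genes was not measured. The 3 ligand genes passed when p was adjusted over the list alone, and the list of 4 genes as a whole did not (median log2 0.73, fry adjusted p = 0.173). Treated tumour 4 carried the highest RNA level of each of these 3 genes. Without that tumour the differences were 0.38 for Cxcl10, 0.65 for Cxcl9 and 0.58 for Cxcl11, and the list median was 0.48. Cxcr3 (Entrez 12766), the receptor, stood at 7.62 ± 0.33 in vehicle and 7.69 ± 0.11 in treated tumours (SD, n = 4 each).

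Among T cell markers, 13 of 14 measured genes had higher mean levels after CXCL10, with a median log2 difference of 0.29. Counts of higher members, here and below, stand against 482 of all 693 genes higher on the authors' scaling. With median-of-ratios scaling 370 of the 693 were higher. Cd96, Sh2d1a (0.43) and the CD3 chain Cd3g (0.43) passed when p was adjusted over the list alone, against 1 of the 14 over all genes. The list did not pass fry's test of a shift in 1 direction (adjusted p = 0.0780 over 27 lists). Its median was 0.18 with median-of-ratios scaling (adjusted p = 0.233), 0.21 with panel median centring (adjusted p = 0.149) and 0.14 with quantile normalization (adjusted p = 0.257). Genes of T cell activation and checkpoints were higher in 16 of 16 members, with a median of 0.24 and an adjusted p of 0.124. Ctla4 and Icos (0.48) passed when adjusted over the list alone. Those same 2 genes were the ones that passed in the list of CD4 helper and regulatory T cells, where 7 of 11 members were higher, the median was 0.11 (0.19 without vehicle tumour 1) and the adjusted p 0.133. In that list Cd4 itself stood at 0.09 and Foxp3 at -0.12. CD8 T cell markers (4 of 4 higher, median 0.47, adjusted p = 0.199) included Cd8a at 0.18, Cd8b1 at 0.59 and Eomes at 0.39 (0.19 without treated tumour 2), and Klrk1 at 0.55 passed within its list. Cytotoxic effector genes (10 of 10 higher, median 0.34, adjusted p = 0.164) included Klrd1 at 0.63, which passed within its list, and Fasl at 0.33, the granzyme gene Gzmk at 0.90 and Prf1 at 0.04, which did not. NK cell markers (15 of 15 higher, median 0.26, or 0.16 without treated tumour 2, adjusted p = 0.167) included Klrc1 at 0.51, Il2rb at 0.48 and Ncr1 at 0.12, and 0 of them passed. Under the same 3 other scalings the medians ran from 0.12 to 0.16 for T cell activation and checkpoints, from 0.0043 to 0.030 for CD4 T cells, from 0.34 to 0.39 for CD8 T cells, from 0.18 to 0.26 for cytotoxic effectors and from 0.11 to 0.18 for NK cells. Klra and Klrc genes resemble each other closely in sequence, so their probes may share signal.

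Interferon-induced genes also had higher means after CXCL10. In the type I interferon list 22 of 25 members were higher, with a median of 0.32 and a fry adjusted p of 0.162. Usp18 (0.50), Ifit2 (0.88), Ifit3 (0.78), Ifit1 (0.94), Isg15 (0.59) and Ifi44 (0.75) passed when adjusted over the list alone, and 0 passed over all genes. The interferon gamma list was higher in 20 of 20 members, with a median of 0.23 (0.14 without treated tumour 4) and an adjusted p of 0.221. Its genes of smallest p were the GTPase gene Irgm2 (0.44), the immunoproteasome gene Psmb9 (0.44) and Ifng itself (0.52), and none passed. MHC class I presentation genes were higher in 11 of 12 members (median 0.23, or 0.12 without vehicle tumour 3, adjusted p = 0.176), and Nlrc5 passed within that list. MHC class II genes went both ways, with 4 of 10 higher, a median of -0.09 (-0.20 to -0.019 with 1 tumour left out) and an adjusted p of 0.938. H2-Ob at 0.59 passed within that list while Cd74 stood at -0.27. Genes of apoptosis and stress were higher in 12 of 13 members, with a median of 0.33 and an adjusted p of 0.0780. Xaf1 (0.50), itself induced by interferon, and the survival gene Bcl2 (0.44) passed within the list. With median-of-ratios scaling, panel median centring and quantile normalization the medians ran from 0.19 to 0.24 for type I interferon, from 0.12 to 0.15 for interferon gamma, from 0.095 to 0.15 for MHC class I, from -0.20 to -0.087 for MHC class II and from 0.19 to 0.25 for apoptosis and stress.

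Markers of vessels and connective tissue lay on the other side. Among endothelial genes 10 of 13 were lower after CXCL10, with a median log2 difference of -0.31. Cdh5, Eng, Vwf (-0.67), Tek (-0.46), Tie1 (-0.41) and Kdr (-0.31) passed when adjusted over the list alone, and 0 passed over all genes. Sele, Vcam1 and Angpt2, which are induced in activated endothelium, stood at 0.25, 0.19 and 0.16. In the list of fibroblasts and matrix 10 of 11 genes were lower, with a median of -0.28 (-0.42 without treated tumour 2). Col4a1, Mmp9, Tgfb3 and Vim (-0.50) passed within the list, and Mmp9 is also made by leucocytes. The other members did not pass: Fap stood at 0.30, Thy1 at -0.03, Col3a1 at -0.04, Fn1 at -0.18, Col1a1 at -0.27, Pdgfrb at -0.28 and Cxcl12 at -0.35. Neither list passed fry's test on the authors' scaling (adjusted p = 0.124 for each). Both passed with median-of-ratios scaling (adjusted p = 0.0310 for each) and with quantile normalization (adjusted p = 0.0227 for each), and the fibroblast list with panel median centring (adjusted p = 0.0336). These other scalings rest on a panel made up largely of immune genes, so a joint rise of such genes would by itself lower the 2 lists. Over all settings of fry's test, tumours left out included, adjusted p ran from 0.0227 to 0.293 for each of the 2 lists. The apoptosis and stress list passed on the higher side with median-of-ratios scaling (adjusted p = 0.0310), quantile normalization (0.0455) and panel median centring (0.0336), and its adjusted p reached 0.235 elsewhere.

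**Figure D2:**
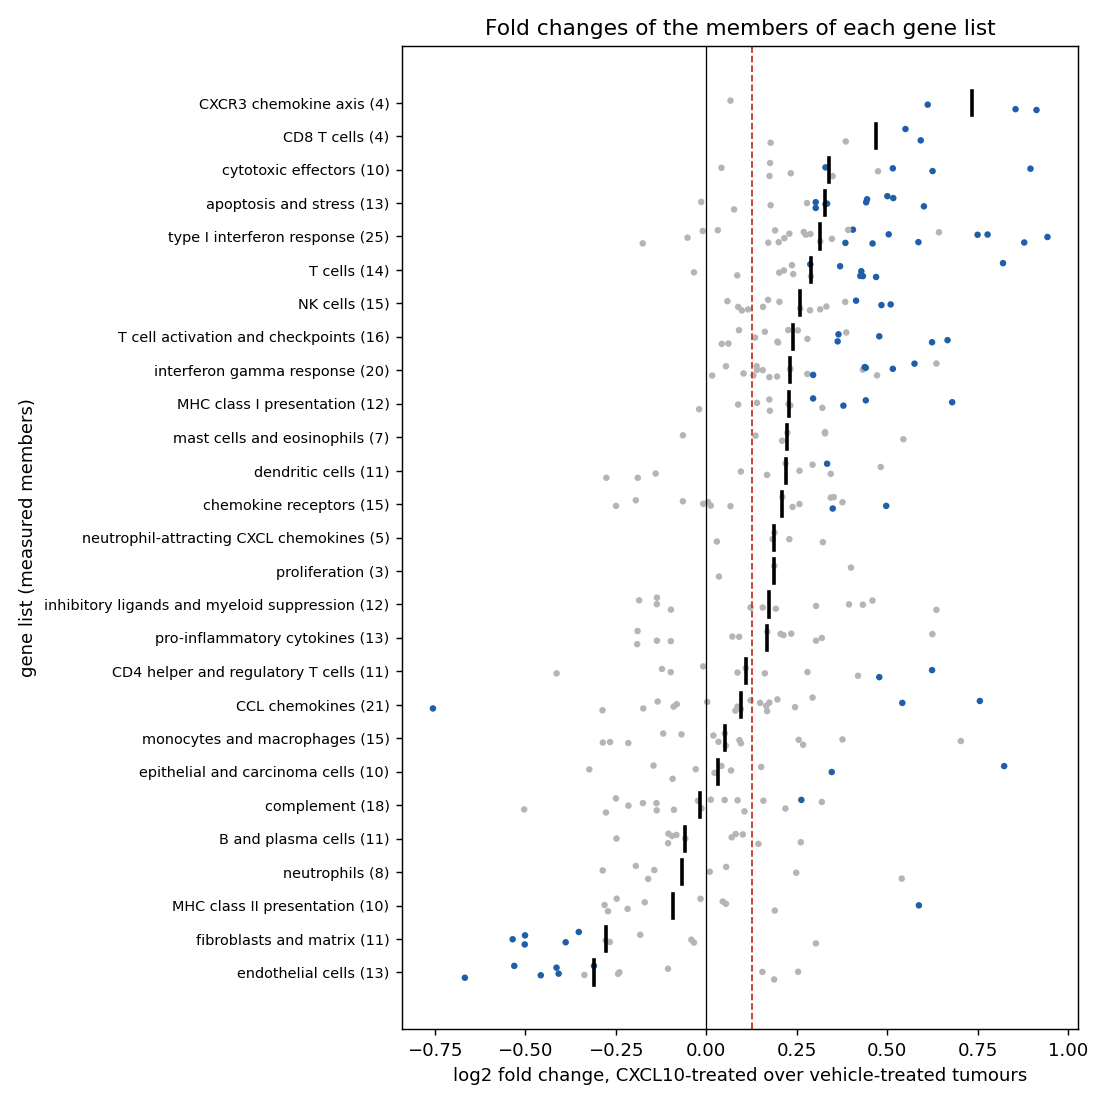
Log2 difference between CXCL10-treated and vehicle-treated tumours (horizontal axis) for each measured member of 27 gene lists (rows, with the number of members), where blue points have an unadjusted p under 0.05, black bars are list medians and the red dashed line is the median of all 693 genes at 0.13. Medians ran from -0.31 for endothelial cells to 0.73 for the CXCR3 chemokine axis, and 0 lists passed fry's test.

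Lists of the other cell types had medians between -0.07 and 0.22, and 0 of their members passed over all genes. Dendritic cell genes had a median of 0.22 (adjusted p = 0.457), with Flt3 at 0.33, and without vehicle tumour 2 the median was 0.088. Mast cell and eosinophil genes had a median of 0.22 (adjusted p = 0.436), with Il5ra at 0.55, and without vehicle tumour 2 these were 0.097 and 0.31. Without treated tumour 3 the median of that list was 0.37. Monocyte and macrophage genes had a median of 0.05 (adjusted p = 0.938), which became -0.05 with median-of-ratios scaling, -0.03 with panel median centring and -0.10 with quantile normalization. Epithelial and carcinoma cell genes likewise went from 0.03 (adjusted p = 0.592) to -0.07, -0.05 and -0.08 in that order, although Anxa1 stood at 0.82. Neutrophil genes had a median of -0.07 and a mean of 0.0092, and fry put them on the lower side (adjusted p = 0.938). B and plasma cell genes had a median of -0.06 and a mean of -0.0027, while fry put them on the higher side (adjusted p = 0.938). Under the same 3 scalings the medians ran from 0.088 to 0.14 for dendritic cells, from 0.087 to 0.15 for mast cells and eosinophils, from -0.17 to -0.15 for neutrophils and from -0.16 to -0.14 for B and plasma cells.

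Soluble mediators and their receptors did not pass either. CCL chemokines had a median of 0.10 (adjusted p = 0.521), or -0.01 with median-of-ratios scaling. They held genes on both sides, with Ccl25 at 0.76, Ccl2, which draws monocytes, at 0.54 and Ccl21a, a chemokine of lymphatic vessels, at -0.75. Neutrophil-attracting CXCL chemokines had a median of 0.19 (adjusted p = 0.503), or 0.068 without treated tumour 4 and 0.37 without vehicle tumour 2. Chemokine receptors had a median of 0.21 (adjusted p = 0.211), or 0.10 without vehicle tumour 2, with Cxcr6, a receptor of effector T cells, at 0.50. Pro-inflammatory cytokines had a median of 0.17 (adjusted p = 0.503), or 0.065 without vehicle tumour 4, and inhibitory ligands and myeloid suppression genes one of 0.17 (adjusted p = 0.550), with Ido1 at 0.64. Without treated tumour 4 the median of that last list was 0.081 and Ido1 stood at 0.34, while without treated tumour 3 the list median was 0.30. The complement list had a median of -0.02 (adjusted p = 0.938), and the 3 measured proliferation genes had one of 0.19 (adjusted p = 0.164), or 0.11 without vehicle tumour 1 and 0.28 without vehicle tumour 2. With the 3 other scalings the medians ran from 0.063 to 0.11 for neutrophil-attracting chemokines, from 0.045 to 0.13 for chemokine receptors, from 0.022 to 0.090 for pro-inflammatory cytokines, from 0.052 to 0.095 for inhibitory ligands and myeloid suppression, from -0.12 to -0.097 for complement and from 0.083 to 0.13 for proliferation.

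**Figure D3:**
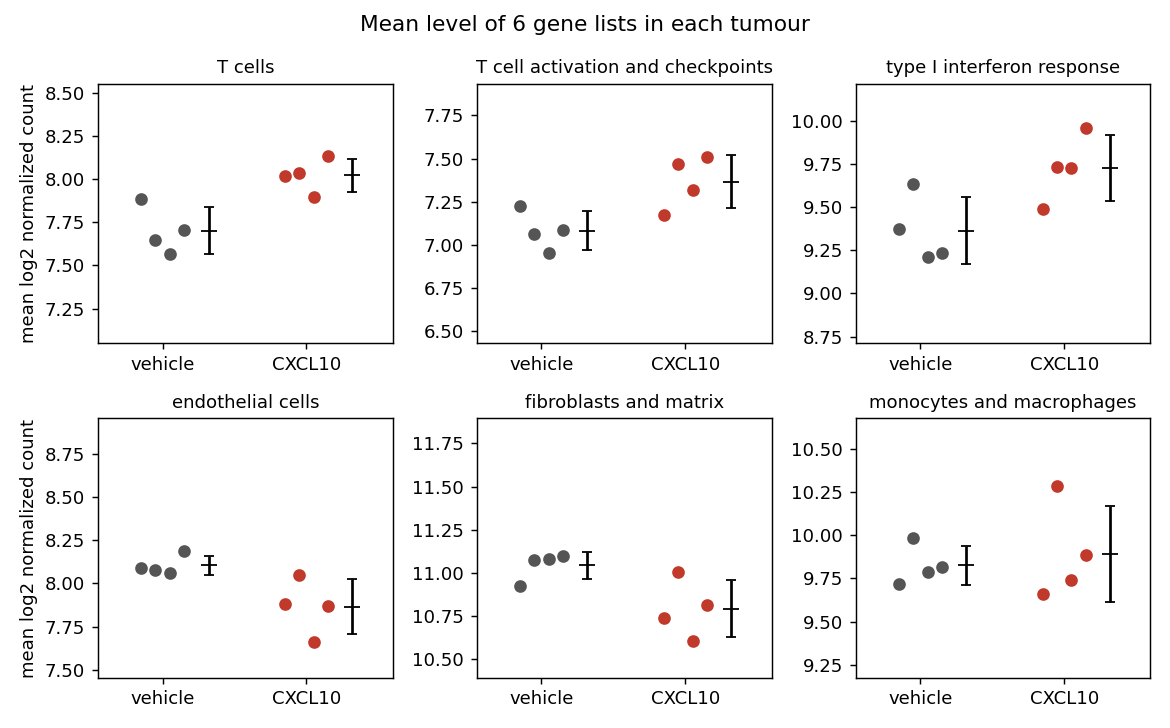
Mean log2 normalized count over the members of 6 gene lists (vertical axes of equal length, not starting at 0) in each of 4 vehicle (grey) and 4 CXCL10-treated tumours (red), with the group mean and SD in black. The T cell list stood at 7.70 ± 0.14 in vehicle and 8.02 ± 0.097 in treated tumours, and the endothelial list at 8.10 ± 0.056 and 7.87 ± 0.16.

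Over the 27 lists, fry called 0 at an adjusted p under 0.05 and gave an unadjusted p under 0.05 for 8. Camera, which sets a list against the rest of the panel, called 6 lists higher (T cells, T cell activation and checkpoints, cytotoxic effectors, type I interferon, interferon gamma, apoptosis and stress) and 2 lower (endothelial cells, fibroblasts and matrix) with its preset correlation of 0.01. With an estimated correlation it called 0 lists (lowest adjusted p = 0.382). Fry's test of change in either direction called 6 lists: T cells and CD4 T cells (adjusted p = 0.00108 each), fibroblasts and matrix (0.00518), apoptosis and stress and T cell activation (0.0118 each) and endothelial cells (0.0185).

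Gene differences can also be set against the median of the whole panel, which is made up largely of immune genes. If immune genes rose together, doing so would take away part of that rise and push other lists down. Which scaling is right was not tested. The median log2 difference of the 693 genes was 0.13 on the authors' scaling, and 482 genes were higher and 211 lower. Relative to that median the T cell list stood at 0.16, the type I interferon list at 0.19, apoptosis and stress at 0.20, CD4 T cells at -0.02, fibroblasts at -0.40 and endothelial cells at -0.44. Of the genes with an unadjusted p under 0.05, 78.8% were higher on the authors' scaling, against 50.4% with median-of-ratios scaling (61 higher, 60 lower), 60.3% with panel median centring (76 higher, 50 lower) and 46.7% with quantile normalization (56 higher, 64 lower). The first 2 of these other scalings called 0 genes at an adjusted p under 0.05, and quantile normalization called Dll4 alone, which fell by 0.65 (adjusted p = 0.0496).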

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

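The values in this part were picked out by a rule on gaps set before the data were examined: a tumour stood apart when its gap to the nearest of the other 3 tumours of its group took up more than a fixed share of the group's range. Of 230 sets of 4 values checked, 10 met it, where chance gives about 1 in 20. The number of sets flagged is therefore no higher than that rate, which holds for independent sets. These sets come from the same tumours, and many of their genes were picked for small p. Whether the number differs from chance was not tested.

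Treated tumour 1 stood low for Cd8b1, a chain of the CD8 receptor, at a log2 level of 4.74 against 5.69 to 5.80 in the other treated tumours. It was also low for Cd80, a co-stimulatory ligand, at 8.52 against 9.00 to 9.04, and for Ccr7, a homing receptor of naive T cells and mature dendritic cells, at 8.14 against 8.503 to 8.526. Treated tumour 2 stood high for Eomes, a transcription factor of cytotoxic lymphocytes, at 7.38 against 6.59 to 6.66, and for the B cell gene Cd22 at 8.10 against 7.36 to 7.42. It was high as well for Cd74, the invariant chain of MHC class II, at 15.97 against 15.51 to 15.59, and for the mean of the mast cell and eosinophil list at 7.44 against 6.93 to 7.01. Vehicle tumour 1 stood high for Icos at 9.40 against 9.09 to 9.13 and low for the mean of the fibroblast and matrix list at 10.93 against 11.08 to 11.10. Vehicle tumour 2 stood high for the chemokine Cxcl2 at 7.67 against 7.002 to 7.115.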

How the results depend on the processing

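Leaving the low-count filter off removed or added 0 genes and so tests nothing. With a pseudocount of 1, Cd96 and Il18r1 were again the genes called. The number of genes called higher went from 2 to 0 with a count minimum of 50 in 4 tumours (631 genes tested, Cd96 not among them, Il18r1 at adjusted p = 0.0670), with a mean-variance trend, voom, median-of-ratios scaling, panel median centring and quantile normalization. The last of these called 1 gene lower. At an adjusted p under 0.10, 4 genes were higher and 1 lower on the authors' scaling, against 6 and 12 with median-of-ratios scaling, 8 and 10 with panel median centring and 5 and 16 with quantile normalization. Cd96 and Il18r1 kept their direction in all these fits that tested them, with log2 differences of 0.62 to 0.82 and 0.48 to 0.59. At an unadjusted p under 0.05, 61 genes were higher and 60 lower with median-of-ratios scaling, 50 were lower with panel median centring, and 56 were higher and 64 lower with quantile normalization. Lists called by fry went from 0 to 1 higher and 2 lower with median-of-ratios scaling and with quantile normalization, and to 1 higher and 1 lower with panel median centring. Camera with its preset correlation called 6 higher and 2 lower, and 0 with an estimated correlation (lowest adjusted p = 0.382). Median-of-ratios scaling and panel median centring subtract 1 value per tumour from all genes, which quantile normalization does not, and the cause of the other changes was not tested. All 5 settings of trend, voom and scaling were chosen after seeing the data. The trend acted on single genes alone.

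Leaving out 1 tumour at a time gave 0 to 3 genes called higher and 0 to 2 lower. The calls came only without vehicle tumour 2, when Cd96, Cd69 and Slamf1 were higher and Clu and Cd207 lower (Cd207 named after its values were seen). At an unadjusted p under 0.05 there were 56 to 132 higher and 17 to 50 lower genes. Called lists numbered 0 to 1 higher (T cells, adjusted p = 0.0405 without vehicle tumour 1) and 0 to 2 lower (endothelial cells and fibroblasts, adjusted p = 0.0467 each without CXCL10 tumour 2). List medians turned sign with 1 tumour left out for B and plasma cells (-0.05 to 0.07), monocytes and macrophages (-0.12 to 0.13), neutrophils (-0.22 to 0.094), epithelial cells (-0.013 to 0.087), CCL chemokines (-0.035 to 0.19) and complement (-0.12 to 0.0061). Tumours with the same number in both groups deviated from their group means with correlations of 0.25, -0.32, 0.23 and -0.26, and 2 of the 4 vehicle tumours correlated best with their own number. These values give no clear sign that the numbers pair the tumours, but are too few to exclude it. With the replicate number as a block, 0 genes were called (lowest adjusted p = 0.175) and 0 lists (lowest adjusted p = 0.164). The planned count models with TMM, median-of-ratios and housekeeping scaling were not run. The deposited count columns matched no sample by name. On the recovered counts voom was run but no count model, although they would have allowed one. Depth limits Cd96, which had 78 counts over the 4 vehicle tumours.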

Other observations

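The tests in this part that were chosen only after the results were seen are those of the receptor families, of counting error, of the T cell and endothelial difference, of the T cell list against 4 other cell types, of harvest day and of the panel medians. The counts over other splits of the tumours were set beforehand.

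Receptors for interleukins on T cells and NK cells were looked at because Il18r1 was among the 2 genes called. All 10 measured genes of that group were higher after CXCL10, with a median log2 difference of 0.44. Il18rap, the second chain of the interleukin-18 receptor, stood at 0.53, Il15ra at 0.54, Il7r at 0.46 and Il12rb1 at 0.43, while Il2rg, the chain shared by several of these receptors, stood at 0.0043. Fry gave an adjusted p = 0.0563 over the 6 families examined in this way, which does not pass, and Il18r1 itself had selected the group. The SLAM family was higher in 7 of 7 genes (median 0.17, adjusted p = 0.386) and receptors of the TNF superfamily in 13 of 14 (median 0.14, adjusted p = 0.185). Ligands of the TNF superfamily had a median of 0.17 (adjusted p = 0.471), integrins one of 0.06 (adjusted p = 0.768) and Toll-like receptors one of 0.02 (adjusted p = 0.808).

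The first pattern weighed is the rise of Cd96 and Il18r1: of the 35 splits of the 8 tumours into 4 and 4, 1 (the treatment groups themselves) called 2 genes and no other split called more than 1. That margin is narrow and comes from the variance model settled on after its calls had been seen, while the trend and voom called 0, so chance is not excluded. Counting error alone is argued against for Cd96, with 78 counts in vehicle and 144 in treated tumours, a ratio between 1.32 and 2.34 (95% exact interval) and an exact binomial p of 0.000121 after adjustment. Cd96 had been picked for its small p. The interval does not allow for that choice and may lie too high. The spread stays open, since the SD between tumours in Cd96 was 0.19 in vehicle and 0.12 in treated tumours, where counting error by itself would give 0.33 and 0.24, and for Il18r1 it was 0.048 and 0.025 where counting error would give 0.069 and 0.055. A candidate explanation for the low p of both genes is therefore a spread that happened to be small in these tumours, and with a mean-variance trend their adjusted p were 0.0707 and 0.0575 (0.0380 to 0.179 and 0.0454 to 0.202 over all settings).

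The second pattern is the T cell list above and the endothelial list below vehicle, 2 lists picked because they stood out, so that p-values for them are not independent evidence of the pattern. The difference between the 2 list means in each tumour went from -0.40 ± 0.13 to 0.16 ± 0.13 (SD, n = 4 each, exact permutation p = 0.0286, the smallest that 4 against 4 can give), and as 1 scaling factor per tumour cannot change it, the authors' scaling did not make this gap, while the T cell list's own median went from 0.29 to between 0.14 and 0.21 under other scalings. A linear effect of the days in the source labels is argued against, since the difference changed by -0.013 per day within groups (SE 0.045) where 0.14 per day would be needed. A lower share of vessel tissue that raises all other cell types alike cannot be told apart from a T cell change, since T cell genes were 0.28 higher relative to 4 other cell types (exact permutation p = 0.0857), with too few tumours to decide. Those 4 were B and plasma cells, monocytes and macrophages, neutrophils and epithelial cells, chosen after the results were seen. The lists of NK cells, mast cells and eosinophils, and dendritic cells were left out, with mean log2 differences of 0.26, 0.24 and 0.15. The 0.28 therefore depends on which cell types were chosen. Chance is not excluded for the number of lists either, as 2 of the 35 splits gave at least the 8 lists seen at an unadjusted p under 0.05, with 10 in the other one, and an effect of the treatment stays open, untested.

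The third pattern is the number of genes with an unadjusted p under 0.05, of which 104 were higher and 28 lower. Their total of 132 was matched or passed by 2 of the 35 splits, the treatment groups included, and the other one gave 168, so chance is not excluded for this total, which counts both directions and says nothing of the lean to the higher side. That split exchanged vehicle tumour 2 and CXCL10 tumour 1 between the groups. On the first principal component, which took 37.4% of the variance, those tumours stood at 1.69 and -0.63, between the other vehicle tumours (-7.45 to -3.17) and the other treated tumours (2.67 to 7.48). Panel medians were 8.66 ± 0.059 in vehicle and 8.74 ± 0.14 in treated tumours (SD, n = 4 each, exact permutation p = 0.286), so a general shift in RNA level and the spread of the medians between tumours cannot be told apart with 4 tumours per group.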
